A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

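Ribosomal RNA-depleted, strand-preserving libraries of total RNA were made by the authors from fission yeast grown in rich medium to an optical density of 0.5, and sequenced as read pairs of 100 nt. There were 4 strains (WT, S2A, S7A and Y1F) with 2 libraries each. The deposited counts were made by the authors as whole numbers of reads per gene ID and library. The notes name HISAT2, featureCounts, StringTie, DESeq2, deepTools and genome build ASM294v2, and the strand setting and versions are not given in the sources used here. Chromatin data of the wider series were not analysed here.

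The table held 7000 gene IDs, of which 271 had 0 counts in every library. By locus tag 6797 matched the reference annotation and 203 did not; unmatched IDs were kept in the gene tests and are named by ID. The annotation at hand is for ASM294v3, a build other than that of the counts, so it gave only names, classes, overlaps and neighbourhoods, and no coordinates are printed. Antisense noncoding RNAs were the 642 of 1420 matched noncoding RNAs (1531 in the table) with at least 50% of their own length opposite a protein-coding gene. Other noncoding RNAs had no opposite overlap, and RNAs with a smaller overlap were in neither list (838 had any).

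Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 6243, scaled by TMM and fitted with a quasi-likelihood model of all 8 libraries with 1 mean per strain, leaving 4 residual degrees of freedom. The common dispersion was 0.00197, a biological coefficient of variation of 4.44%. Each mutant was compared with WT and with each other mutant, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. DESeq2 1.42.0 served as an alternative. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

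The lists were RNA polymerase II subunits; CTD kinases, phosphatases and readers; 3′ end processing and termination; Set2 and Clr6 complex II; RNA surveillance and RNAi; phosphate regulon; Ste11 and early sexual differentiation; M-cell and P-cell mating genes; meiosis; core stress response; chaperones; iron acquisition; copper uptake; thiamine; nitrogen response; hexose transport and glucose derepression; flocculins; cell separation; MBF targets; histones; cytosolic ribosomal proteins; ribosome biogenesis; nuclear-encoded respiratory chain; Tf2 retrotransposons; auxotrophic marker genes; mitochondrial genome; small nuclear and nucleolar RNAs; all, antisense and other noncoding RNAs; protein-coding genes with an antisense RNA; and subtelomeric genes, within 100 kb of the ends of chromosomes I and II. The list called flocculins also held cbf12 and mbx2, which do not encode flocculins. The grouping, comparisons, lists and other settings to be tried were set before the data were examined.

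Named genes followed a rule. It took rpb1 first, then for each mutant against WT up to 8 protein-coding genes each way with the largest change among called genes of at least 5 CPM whose mutant libraries both lay on the same side of both WT libraries. It added up to 3 noncoding RNAs each way of at least 1 CPM, and up to 4 called members of each list that was called or had at least 3 called members, or up to 2 for lists defined by ID, position or symbol pattern. ste11, mei2, pho1, pho84, tgp1, lsk1, set2 and pcf11 were always taken, and pairs of mutants gave up to 4 genes each way. rpb3 and the genes opening the observations were chosen after their values were seen. For a gene at 0 counts in a strain the fold change was bounded with 3 counts over the group, and for 1 to 3 counts an exact counting interval is given.

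Recovery was tested on simulated data with 50 genes changed at each of 4 fold sizes, 200 genes in all. The changed genes were drawn from those with a WT mean above 1 CPM, so the rates do not cover genes below that. Far more genes were called in the data, a case these simulations do not cover either. For S2A against WT 56%, 84%, 96% and 100% were recovered at 1.25-, 1.5-, 2- and 4-fold, with 15 false among 183 calls. For S7A the rates were 54%, 88%, 100% and 100% (10 false among 181), and for Y1F 74%, 90%, 94% and 98% (15 false among 193).

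Changes of antisense RNAs and the genes opposite them were related by Spearman correlation with 100000 permutations, adjusted over the 3 mutants. The other settings were DESeq2, RLE scaling, scaling on protein-coding genes only, no filter, a filter of at least 5 CPM in at least 2 libraries, fitting only the compared groups, a replicate block, a 2-fold threshold, leaving out each library in turn, the estimated correlation for lists, another denominator for shares, protein-coding genes only for agreement between mutants, and any overlap for antisense pairs. Shares without SPNCRNA.98, and the subtelomeric list (at both correlations) and Y1F count without the run of adjacent genes, were added after the data were seen.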

Results

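Total RNA was profiled in Schizosaccharomyces pombe, the fission yeast, in 4 strains with 2 libraries each (8 libraries). All strains were of the h- mating type and carried an epitope-tagged Rpb3, a subunit of RNA polymerase II. The wild-type reference (WT) kept the normal Rpb1, whose C-terminal domain is a run of 7-residue repeats that is phosphorylated as genes are transcribed. In the mutants the repeats were changed at serine 2 to alanine (S2A), serine 7 to alanine (S7A) or tyrosine 1 to phenylalanine (Y1F). The study asked what serine 2 phosphorylation does, with transcription from the antisense strand and RNA 3′ end formation as the processes of interest. The deposited table held 15699008 and 14620548 counts for WT replicates 1 and 2, 20075620 and 14830660 for S2A, 16780896 and 23081870 for S7A, and 13391705 and 21986870 for Y1F. Levels below are CPM (counts scaled to a common library size) after TMM scaling, given as mean ± SD with n = 2, and changes are log2 fold changes ± SE. The SE was derived from the test, as the size of the change divided by the square root of its F statistic. For genes near 0 counts in a strain it can be too small. In Y1F, gal1 moved from −8.13 to −8.73 or −7.48 without Y1F replicate 1 or 2, by more than its SE.

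The transcript of the mutated gene was measured in every library. rpb1 (SPBC28F2.12) stood at 720 and 691 CPM in the WT libraries, at 387 and 382 in S2A, at 377 and 388 in S7A, and at 450 and 449 in Y1F. It was lower than WT in each mutant, by −0.88 ± 0.044 in S2A (adjusted p = 1.20e-08), −0.88 ± 0.044 in S7A (adjusted p = 2.24e-08) and −0.65 ± 0.044 in Y1F (adjusted p = 3.60e-07). The mutant alleles carried a kanMX6 marker at rpb1 that WT lacked, so the residue change and the marker cannot be separated here, and gene counts do not show the substitutions themselves. rpb3 (SPCC1442.10c), tagged in all strains, was at 106 ± 0.279 CPM in WT, 192 ± 2.45 in S2A, 97.2 ± 1.73 in S7A and 230 ± 8.62 in Y1F. Its change was 0.86 ± 0.044 in S2A (adjusted p = 1.39e-08) and 1.13 ± 0.044 in Y1F (adjusted p = 2.53e-09); the small S7A difference (−0.12, adjusted p = 0.0474) was not rerun under the alternatives.

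Of 6243 genes tested, 3458 differed between S2A and WT at an adjusted p under 0.05, 1799 of them higher and 1659 lower (1938 and 1520 with scaling on protein-coding genes), and 658 of them by at least 2-fold. In S7A 2957 differed (1443 higher, 1514 lower; 395 by at least 2-fold). In Y1F 2186 differed (1098 higher, 1088 lower; 271 by at least 2-fold), and the count was 1203, 1574 and 1552 without Y1F replicate 2, Y1F replicate 1 and WT replicate 1, with 1166, 1528 and 1436 of these also called with all libraries. DESeq2 called fewer genes: 2789 in S2A (1417 higher, 1372 lower), 2209 in S7A (1085 higher, 1124 lower) and 1523 in Y1F (647 higher, 876 lower). The first principal component of log2 CPM held 50.6% of the variance and set both S2A libraries apart from the other 6, the second (23.7%) parted S7A from Y1F, and the third (17.8%) parted WT from the mutants. Replicates had Spearman correlations across genes of 0.9976 (WT) to 0.9988 (S7A), and still differed by more than sampling noise (chi-square per gene from 5.04 in Y1F to 11.7 in WT). The labels do not say that the libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

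Antisense noncoding RNAs rose widely in S2A. The class holds each annotated noncoding RNA that overlaps a protein-coding gene of the other strand by at least 50% of its own length. Of 584 such RNAs tested, 374 were higher than in WT, 63 were lower and 147 were not called, with a median change of 0.88, which stayed 0.88 with RNAs at 0 counts in a strain set to their bound. Their share of all counts was 0.330 ± 0.0095% in WT and 0.631 ± 0.0142% in S2A (SD, n = 2), against 0.284 ± 0.0016% in S7A and 0.349 ± 0.0023% in Y1F. Shares are given as values without a test; with 2 libraries a side the smallest p of an exact two-sided permutation test is 0.333. As a list, the antisense RNAs rose in S2A (camera adjusted p = 1.62e-21), with 378 higher and 67 lower when adjusted over the list alone. The adjusted p = 0.138 with an estimated correlation. Other noncoding RNAs, those with no overlap with a protein-coding gene on the opposite strand, were not called as a list (66 higher, 71 lower of 324; adjusted p = 0.674). All 1104 noncoding RNAs together rose (488 higher, 180 lower; 489 and 182 adjusted over the list alone; median 0.38, or 0.37 with bounds; camera adjusted p = 1.10e-06). The adjusted p = 0.408 with an estimated correlation.

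Single noncoding RNAs changed far more than these medians. SPNCRNA.818 rose from 0.1996 ± 0.0881 to 11.7 ± 1.15 CPM (5.81 ± 0.334, adjusted p = 3.40e-08), and SPNCRNA.569 from 0.236 ± 0.0553 to 10.3 ± 1.69 CPM (5.43 ± 0.311, adjusted p = 3.28e-08). SPNCRNA.820 had 3 counts in WT and 171 in S2A, a ratio of 48.1 with a 95% counting interval of 16.2 to 236. With 0 counts in WT, prl61 was at least 11-fold higher and SPNCRNA.842 at least 7.88-fold higher in S2A, taking 3 counts over the group as the floor. The model's own value for prl61 was 7.30, against 6.62 without S2A replicate 2 and 6.57 with DESeq2, and for SPNCRNA.842 6.81, against 6.001 with DESeq2. SPNCRNA.842 was also higher in S7A (model value 5.57, 4.76 with DESeq2). In Y1F it was at 5.78 (4.84 with DESeq2, 4.38 without Y1F replicate 2). SPNCRNA.1309 fell from 5.30 ± 0.463 to 0.596 ± 0.0181 CPM (−3.14 ± 0.293) and SPNCRNA.1307 from 4.90 ± 0.449 to 0.819 ± 0.0103 CPM (−2.57 ± 0.263). omt3 fell from 8.09 ± 0.509 to 0.155 ± 0.124 CPM (−5.52 ± 0.331, adjusted p = 4.77e-08; −6.75 without S2A replicate 1). Counting intervals and floors cover counting error only. The library kit keeps strand, but the strand setting used for counting is not given in the sources used here, so values of overlapping genes on opposite strands are uncertain to that extent.

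**Figure D1:**
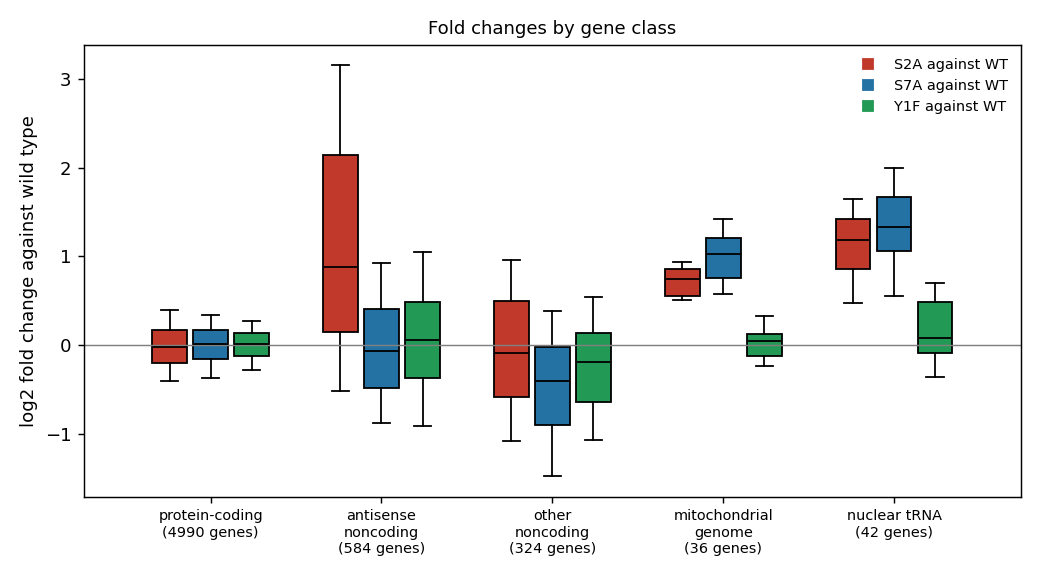
Log2 fold change of each mutant against WT (vertical axis) for 5 classes of tested genes: 4990 protein-coding genes, 584 antisense noncoding RNAs, 324 other noncoding RNAs, 36 mitochondrial genes and 42 nuclear transfer RNA genes. Boxes span the quartiles with the median as a line, and whiskers reach the 10th and 90th percentiles; the antisense median was 0.88 in S2A, −0.07 in S7A and 0.05 in Y1F.

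Several regulators of sexual differentiation were lower in the S2A strain. mei2, an RNA-binding regulator of meiotic entry, fell from 82.8 ± 7.60 to 9.82 ± 1.45 CPM (−3.06 ± 0.131, adjusted p = 3.59e-09), and ste11, the transcription factor that starts sexual differentiation, from 77.1 ± 6.01 to 19.9 ± 3.48 CPM (−1.94 ± 0.107, adjusted p = 2.44e-08). ste4, a component of the pheromone MAP kinase pathway, changed by −2.68 ± 0.130, and gpa1, the pheromone-response G protein alpha subunit, by −1.52 ± 0.081. The Ste11 and early differentiation list fell with a median of −0.71: 5 of 10 members were lower, 3 higher and 2 not called, with the same counts adjusted over the list alone (camera adjusted p = 1.30e-06). The adjusted p = 0.429 with an estimated correlation. mfm2, encoding a precursor of the M-cell mating pheromone, fell from 36.1 ± 2.02 to 2.92 ± 0.684 CPM (−3.59 ± 0.151, adjusted p = 3.40e-09). It drove its list: of 6 M-cell mating genes 2 were lower and 2 higher, also adjusted over the list alone, with a median of 0.00, a mean of −0.55 and a camera test pointing down (adjusted p = 0.0413). The adjusted p = 0.429 with an estimated correlation; the call was lost without WT replicate 2 (0.0526), S2A replicate 1 (0.0744) or S2A replicate 2 (0.0509), and with a replicate block (0.0502). Of 4 P-cell mating genes, 2 were higher and 1 lower (adjusted p = 0.788).

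The meiosis list rose in S2A. dmc1, the meiotic recombinase, rose from 1.04 ± 0.107 to 12.4 ± 0.162 CPM (3.57 ± 0.194, adjusted p = 2.17e-08), the sporulation septin spn6 from 0.941 ± 0.126 to 8.49 ± 0.516 CPM (3.17 ± 0.214, adjusted p = 1.34e-07), and meu14, which acts at the forespore membrane, from 2.18 ± 0.216 to 13.42 ± 1.65 CPM (2.63 ± 0.190). Of 22 meiosis genes 12 were higher, 3 lower and 7 not called, with the same counts adjusted over the list alone (median 0.34, camera adjusted p = 0.00357). The adjusted p = 0.329 with an estimated correlation. Outside the lists, mug62 rose by 4.22 ± 0.222 and meu27 by 4.09 ± 0.189, and crp79 rose from 2.32 ± 0.220 to 17.0 ± 1.63 CPM. The largest change of a protein-coding gene above 5 CPM was in gdt1 (SPAC186.05c), from 0.265 ± 0.181 CPM in WT to 72.1 ± 2.30 in S2A (8.04 ± 0.179, adjusted p = 2.99e-11; 8.97 without WT replicate 1).

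The core stress list rose in S2A, with 6 of its 15 genes not called. hsp16, a small heat shock protein, went from 56.3 ± 4.41 to 230 ± 12.9 CPM (2.03 ± 0.060, adjusted p = 2.81e-10), and cta3 rose by 1.44 ± 0.172. The chaperone list was not called (3 higher, 1 lower and 9 not called of 13; adjusted p = 0.788), though its Hsp70 gene ssa1 went from 59.8 ± 33.0 to 207 ± 48.4 CPM (1.81 ± 0.291, adjusted p = 0.000211; 2.51 without WT replicate 2). Of 15 core stress genes 8 were higher, 1 lower and 6 not called (8 and 2 adjusted over the list alone; median 0.44, camera adjusted p = 0.00676). The adjusted p = 0.499 with an estimated correlation. Among 8 cell separation genes 6 were lower, 0 higher and 2 not called (7 lower adjusted over the list alone; median −0.38, camera adjusted p = 0.00395). The adjusted p = 0.525 with an estimated correlation. They included eng1 (−0.72 ± 0.049) and agn1 (−0.52 ± 0.054), whose glucanases dissolve the division septum. The nitrogen response list fell, 7 of 10 lower, 0 higher and 3 not called, also adjusted over the list alone (median −0.30, camera adjusted p = 0.0253), with the proline permease put4 at −1.52 ± 0.104 and isp5 at −1.05 ± 0.161. The adjusted p = 0.472 with an estimated correlation, and without S2A replicate 1 it was 0.0657.

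Of 131 cytosolic ribosomal protein genes 75 were lower in S2A, 0 higher and 56 not called, also adjusted over the list alone (median −0.19, camera adjusted p = 6.75e-06). The adjusted p = 0.896 with an estimated correlation. The largest falls were in rps1401 (−1.38 ± 0.058) and rps2202 (−1.11 ± 0.048); these genes have near-identical copies, so reads may be split between them. The auxotrophic marker genes, listed as a sign of strain background, fell slightly (5 of 6 lower, 0 higher, 1 not called, also adjusted over the list alone; median −0.32, camera adjusted p = 0.0253). The adjusted p = 0.638 with an estimated correlation; the call was lost without WT replicate 1 (0.0520) or S2A replicate 1 (0.0552). Mitochondrial genome transcripts rose, 34 of 36 higher, 0 lower and 2 not called, also adjusted over the list alone (median 0.74, camera adjusted p = 4.94e-06). The adjusted p = 0.758 with an estimated correlation. Of 42 nuclear transfer RNA genes, a class outside the lists, 24 were higher and 0 lower (median 1.19). The mitochondrial share of counts was 2.40 ± 0.423% in WT and 3.51 ± 0.0776% in S2A (SD, n = 2), and the transfer RNA share 0.0042 ± 0.0008% and 0.0090 ± 0.0019%.

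Lists on transcription and RNA processing were not called in S2A. Of 17 genes of 3′ end processing and termination 6 were higher and 2 lower (adjusted p = 0.788), with pcf11, a cleavage and termination factor, at 0.30 ± 0.046 (adjusted p = 0.000137). Of 19 CTD kinases, phosphatases and readers 2 were higher and 4 lower (adjusted p = 0.788), with the serine 2 kinase lsk1 at 133 ± 1.45 CPM against 90.2 ± 0.568 (0.56 ± 0.043, adjusted p = 3.87e-07). Of 12 polymerase II subunits 6 were higher and 2 lower (adjusted p = 0.788). Of the 7 genes of Set2 and Clr6 complex II 2 were higher and 1 lower (adjusted p = 0.828); set2, the H3K36 methyltransferase, had −0.09 ± 0.044 (adjusted p = 0.113; −0.13, adjusted p = 0.0312, without WT replicate 2). RNA surveillance and RNAi had 4 higher and 4 lower of 12 (adjusted p = 0.992; median −0.04, mean 0.01).

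Among nutrient genes, the phosphate list had 1 of 3 higher and 1 lower in S2A (adjusted p = 0.788): tgp1, a glycerophosphodiester transporter, was at 0.88 ± 0.127 (adjusted p = 8.79e-05), the acid phosphatase pho1 at 0.15 ± 0.108 (adjusted p = 0.265), and the phosphate transporter pho84 at −0.34 ± 0.086 (adjusted p = 0.00486). The pho1 value was 0.37 (adjusted p = 0.00433) without WT replicate 1 and −0.04 (adjusted p = 0.695) without WT replicate 2, and pho84 was not called without WT replicate 1 (−0.20, adjusted p = 0.0597) or S2A replicate 1 (−0.27, adjusted p = 0.0560). Iron acquisition had 5 higher and 1 lower of 9 (adjusted p = 0.161; 0.0248 without Y1F replicate 1 and 0.0257 without Y1F replicate 2), copper uptake 1 higher and 0 lower of 3 (0.788), thiamine 1 higher and 3 lower of 5 (0.788; median −0.18, mean 0.64), with nmt1 at 3.98 ± 0.412, and hexose transport 1 higher and 0 lower of 11 (0.788). Flocculins had 5 higher and 1 lower of 10 (adjusted p = 0.0712; 0.0116 without S2A replicate 1), with pfl3 at 1.34 ± 0.066 and pfl7 at −3.10 ± 0.262. Also uncalled were MBF targets (1 higher and 2 lower of 9; 0.788; median 0.03, mean −0.00), histones (1 and 2 of 10; 0.788), ribosome biogenesis (1 and 12 of 37; 0.157), nuclear-encoded respiratory chain (16 and 2 of 46; 0.561) and Tf2 retrotransposons (3 and 0 of 5, near-identical copies; 0.561). The same held for small nuclear and nucleolar RNAs (4 and 3 of 44; 0.869) and subtelomeric genes, within 100 kb of an end of chromosome I or II (33 and 26 of 80; 0.788).

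The 581 pairs of an antisense RNA and the protein-coding gene it overlaps were used to ask whether the sense gene fell where its antisense RNA rose. In S2A the changes had a Spearman rho of −0.144 across pairs (permutation p = 0.00058, adjusted p = 0.00174 over the 3 mutants), and genes are not independent replicates. Of 373 pairs whose antisense RNA was higher, the sense gene was lower in 137 (36.7%), higher in 80 and not called in 156. Of 145 pairs whose antisense RNA was not called, the sense gene was lower in 40 (27.6%) and higher in 43. The same shares, sense gene lower beside a higher and beside an uncalled antisense RNA, were 39.2% of 79 and 24.2% of 368 in S7A and 24.5% of 106 and 18.7% of 380 in Y1F, and their differences were not tested in any mutant. In S7A rho was −0.052 (permutation p = 0.209, adjusted p = 0.209) and in Y1F −0.083 (permutation p = 0.0450, adjusted p = 0.0675). With any overlap taken, rho was −0.109 in S2A, 0.013 in S7A and −0.033 in Y1F (permutation adjusted p = 0.003, 0.694 and 0.47). As a list, the 618 protein-coding genes with an antisense RNA were not called in S2A (151 higher, 206 lower; camera adjusted p = 0.322; median −0.04, mean 0.02).

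In S7A the phosphate genes rose most among the lists. tgp1 went from 23.08 ± 2.92 CPM in WT to 215 ± 14.99 (3.22 ± 0.111, adjusted p = 1.28e-09), pho1 from 238 ± 47.0 to 952 ± 87.5 CPM (2.00 ± 0.109, adjusted p = 4.49e-08) and pho84 from 1525 ± 199 to 1876 ± 62.8 CPM (0.30 ± 0.085, adjusted p = 0.0124). All 3 members were thus higher, also adjusted over the list alone (median 2.00, camera adjusted p = 1.85e-10). The adjusted p = 0.277 with an estimated correlation. The pho84 call was lost without WT replicate 2 (0.17, adjusted p = 0.0985) or S7A replicate 2 (0.26, adjusted p = 0.0818) and with DESeq2 (adjusted p = 0.0568). Core stress genes rose as a list: 11 of 15 were higher, 2 lower and 2 not called, also adjusted over the list alone (median 0.68, camera adjusted p = 2.01e-09). The adjusted p = 0.277 with an estimated correlation. cta3, a cation-transporting ATPase, rose from 3.88 ± 0.533 to 30.98 CPM (3.00 ± 0.149), hsp16 by 1.44 ± 0.060, hsp9 by 1.13 ± 0.087 and the catalase gene ctt1 by 1.11 ± 0.052.

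The Ste11 list, but not every mating list, was lower in the S7A strain. mei2 fell from 82.8 ± 7.60 to 20.2 ± 3.13 CPM (−2.04 ± 0.116, adjusted p = 6.29e-08), ste4 by −1.33 ± 0.109 and rgs1, a regulator of pheromone G protein signalling, by −1.13 ± 0.072. ste11 itself was at 59.6 ± 6.23 against 77.1 ± 6.01 CPM (−0.38 ± 0.093, adjusted p = 0.00554; not called without S7A replicate 2, −0.27, adjusted p = 0.0804). It had 7 of 10 members lower, 0 higher and 3 not called, also adjusted over the list alone (median −0.39, camera adjusted p = 6.27e-05). The adjusted p = 0.370 with an estimated correlation. The M-cell list fell narrowly (2 of 6 lower, 0 higher, 4 not called, also adjusted over the list alone; median −0.30, camera adjusted p = 0.0494), with mfm2 at −1.37 ± 0.115. The adjusted p = 0.341 with an estimated correlation; the call was lost with normalization on protein-coding genes (0.0541), with a replicate block (0.0576), and without WT replicate 1 (0.0637), WT replicate 2 (0.0957), S2A replicate 1 (0.0518), S2A replicate 2 (0.0536), S7A replicate 2 (0.0895), Y1F replicate 1 (0.0601) or Y1F replicate 2 (0.0604). P-cell mating genes (2 higher, 2 lower of 4; adjusted p = 0.963) and meiosis genes (8 higher, 5 lower of 22; adjusted p = 0.340) were not called as lists, though spn6 rose by 2.92 ± 0.217 and meu27, outside the list, by 3.00 ± 0.208.

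Thiamine genes fell in S7A, 4 of 5 lower, 0 higher and 1 not called, also adjusted over the list alone (median −0.45, camera adjusted p = 0.000824), with the thiamine transporter thi9 at −1.32 ± 0.072. The adjusted p = 0.341 with an estimated correlation. Of 10 genes of the flocculin list 4 were lower, 0 higher and 6 not called, also adjusted over the list alone (median −0.19, camera adjusted p = 0.0132). The adjusted p = 0.341 with an estimated correlation. The lower members were pfl7 at −2.96 ± 0.252, pfl3 at −1.42 ± 0.073, pfl5 at −0.30 and cbf12 at −0.28. Without WT replicate 2 pfl5 was at −0.21, and cbf12 was at −0.20 without WT replicate 1 and −0.14 without S7A replicate 1. fio1, an iron oxidase, fell from 180 ± 17.3 to 44.1 ± 9.47 CPM (−2.04 ± 0.324, adjusted p = 0.000297) and its partner permease fip1 by −1.84 ± 0.332, as 2 of 5 lower members of the 9 iron acquisition genes. That list had 1 member higher and an adjusted p of 0.0968, which was 0.00625 without WT replicate 1, 5.04e-05 without Y1F replicate 1 and 5.25e-05 without Y1F replicate 2. Other large changes were in SPBC19C7.04c (11.6 ± 0.911 to 94.2 ± 5.20 CPM; 3.03 ± 0.079), SPCC737.04 (2.57 ± 0.123), otg2 (2.38 ± 0.174) and mug147 (2.07 ± 0.100). SPBPB10D8.02c fell from 22.9 ± 5.56 to 0.640 ± 0.0261 CPM (−5.15 ± 0.295, adjusted p = 6.77e-08), SPBPB10D8.01 by −4.31 ± 0.140, SPBPB21E7.09 by −2.46 ± 0.147 and nrg1 by −2.06 ± 0.123. All 4 are subtelomeric, but subtelomeric genes were not called as a list in S7A (21 higher, 26 lower and 33 not called of 80; adjusted p = 0.0865, or 0.00625 without WT replicate 1).

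Ribosomal protein genes fell in S7A, 84 of 131 lower, 0 higher and 47 not called (91 lower adjusted over the list alone; median −0.22, camera adjusted p = 2.01e-09), with rpl1603 at −1.29 ± 0.048 and rps2202 at −1.19 ± 0.048, both with near-identical copies. The adjusted p = 0.729 with an estimated correlation. Ribosome biogenesis fell narrowly (18 of 37 lower, 1 higher, 18 not called, also adjusted over the list alone; median −0.12, camera adjusted p = 0.0494). The adjusted p = 0.641 with an estimated correlation, and the call was lost without WT replicate 1 (0.0866), S2A replicate 1 (0.0542), S2A replicate 2 (0.0537) or S7A replicate 2 (0.0893). Histone genes, several of them near-identical, rose narrowly (5 of 10 higher, 0 lower, 5 not called, also adjusted over the list alone; median 0.18, camera adjusted p = 0.0494). The adjusted p = 0.341 with an estimated correlation; the call was lost with normalization on protein-coding genes (0.0520), with a replicate block (0.0510), and without WT replicate 2 (0.0776), S2A replicate 1 (0.0518), S2A replicate 2 (0.0537), S7A replicate 2 (0.0893), Y1F replicate 1 (0.0601) or Y1F replicate 2 (0.0604). All 36 mitochondrial genome transcripts were higher, also adjusted over the list alone (median 1.02, camera adjusted p = 4.16e-20). The adjusted p = 0.341 with an estimated correlation. Of 42 nuclear transfer RNA genes 30 were higher and 0 lower (median 1.33). The mitochondrial share of counts was 3.60 ± 0.0674% and the transfer RNA share 0.0103 ± 0.0003% (SD, n = 2).

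Antisense noncoding RNAs did not rise as a class in S7A. Of 584 RNAs 79 were higher, 136 lower and 369 not called (camera adjusted p = 0.408; median −0.07, mean 0.01). Other noncoding RNAs fell, 106 of 324 lower, 20 higher and 198 not called (102 and 18 adjusted over the list alone; median −0.40, also with bounds; camera adjusted p = 0.00135). The adjusted p = 0.434 with an estimated correlation. All noncoding RNAs fell as well, 321 of 1104 lower, 110 higher and 673 not called (303 and 101 adjusted over the list alone; median −0.23, also with bounds; camera adjusted p = 0.0107). The adjusted p = 0.411 with an estimated correlation, and it was 0.0747 without WT replicate 2. SPNCRNA.231 rose from 0.134 ± 0.00451 to 5.75 ± 0.0873 CPM (5.35 ± 0.351, adjusted p = 5.83e-07) and SPNCRNA.234 from 0.573 ± 0.161 to 14.6 ± 0.285 CPM (4.67 ± 0.258), while SPNCRNA.232, at 0 counts in WT, was at least 8.88-fold higher (model value 6.99, against 6.20 with DESeq2). SPNCRNA.1307 fell from 4.90 ± 0.449 to 0.321 ± 0.139 CPM (−3.97 ± 0.312) and SPNCRNA.1308 from 17.7 ± 2.54 to 2.70 ± 0.263 CPM (−2.70 ± 0.196). The genes of the 3′ end processing list (7 higher, 3 lower of 17) were not called as a list (adjusted p = 0.340). lsk1 was at 0.06 ± 0.043 (adjusted p = 0.265).

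Small changes of set2 and pcf11 passed the threshold in S7A, and most settings kept their size but not their calls. set2 was at −0.12 ± 0.044 (adjusted p = 0.0426) and lost its call without WT replicate 1 (−0.06, 0.327), S2A replicate 1 (−0.11, 0.0627), S2A replicate 2 (−0.11, 0.0646), S7A replicate 1 (−0.12, 0.125), S7A replicate 2 (−0.11, 0.173), Y1F replicate 1 (−0.12, 0.0574) or Y1F replicate 2 (−0.12, 0.0561), with RLE scaling (−0.11, 0.0532), with only the compared groups fitted (−0.11, 0.0834) and with DESeq2 (−0.11, 0.158). pcf11 was at −0.13 ± 0.047 (adjusted p = 0.0386) and lost its call without WT replicate 1 (−0.13, 0.0872), WT replicate 2 (−0.12, 0.0949), S2A replicate 1 (−0.12, 0.0553), S2A replicate 2 (−0.12, 0.0530), S7A replicate 1 (−0.09, 0.262), Y1F replicate 1 (−0.13, 0.0554) or Y1F replicate 2 (−0.13, 0.0548), with only the compared groups fitted (−0.12, 0.0784) and with DESeq2 (−0.12, 0.207).

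**Figure D2:**
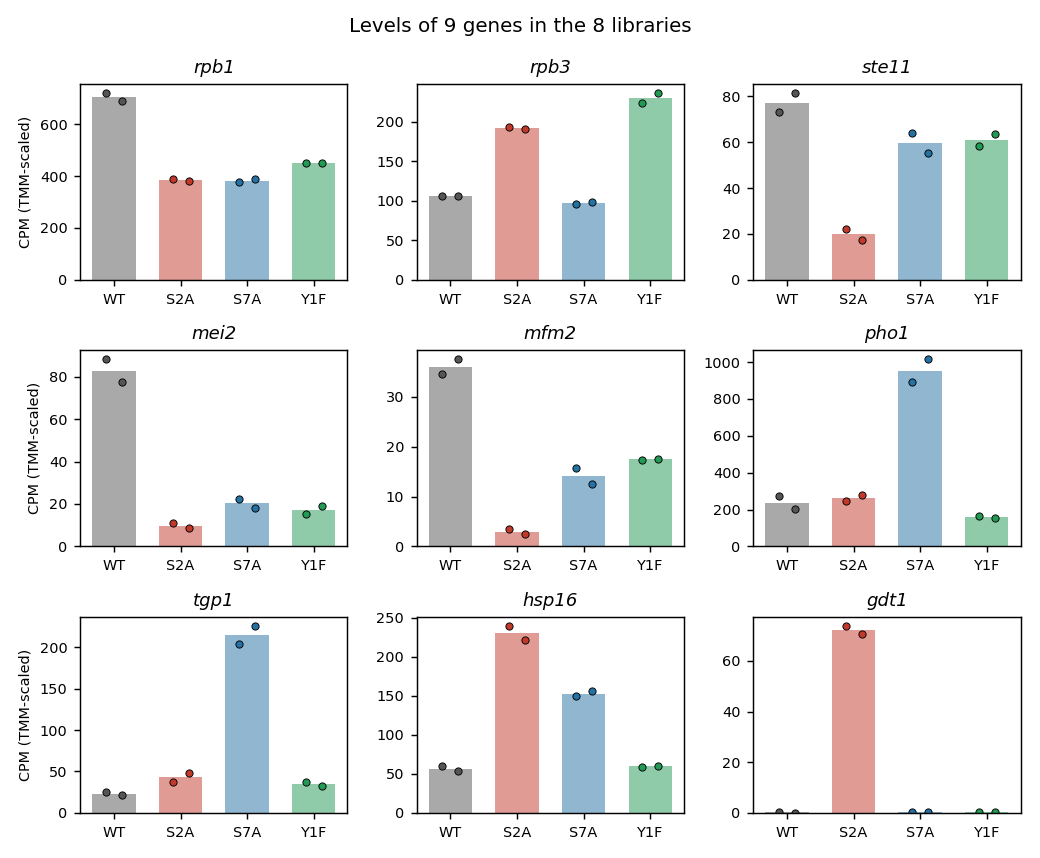
TMM-scaled CPM of 9 genes (rpb1, rpb3, ste11, mei2, mfm2, pho1, tgp1, hsp16 and gdt1) in the 4 strains, with bars for the mean and points for the 2 libraries. mei2 stood at 82.8 CPM in WT and at 9.82, 20.2 and 17.1 CPM in S2A, S7A and Y1F, while pho1 and tgp1 were highest in S7A (952 and 215 CPM) and gdt1 was above 1 CPM in S2A alone (72.1 CPM).

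In Y1F the largest changes fell in a run of neighbouring subtelomeric genes on chromosome II. gal1, a galactokinase gene, went from 40.7 ± 0.576 CPM in WT to 0.155 ± 0.0931 (−8.13 ± 0.175, adjusted p = 9.97e-12), pan5 from 93.4 ± 3.05 to 0.236 ± 0.0823 (−8.68 ± 0.135, adjusted p = 3.58e-13) and gal10, also of galactose metabolism, from 8.66 ± 0.670 to 0.140 ± 0.0098 (−5.90 ± 0.292, adjusted p = 2.76e-08). nrg1 fell by −7.15 ± 0.238 and SPBPB2B2.06c by −6.53 ± 0.419. SPBPB2B2.05 and say1 each had 1 count in Y1F and were lower by ratios of 288 (95% counting interval 51.3 to 11440) and 219 (38.9 to 8710). The noncoding RNAs of the run behaved alike, with nam3 going from 23.9 ± 3.36 to 0.706 ± 0.559 CPM (−5.27 ± 0.270) and SPNCRNA.1697 having 3 counts in Y1F, a ratio of 65.0 (21.9 to 319). Leaving out Y1F replicate 1 or 2 moved gal1 to −8.73 or −7.48 and nam3 to −6.23 or −4.43, and leaving out Y1F replicate 2 moved SPBPB2B2.06c to −7.38. The model values behind the ratios moved likewise, from −7.85 to −10.08 for SPBPB2B2.05 without Y1F replicate 2, from −7.45 to −9.79 or −6.23 for say1 and from −5.90 to −6.72 or −5.13 for SPNCRNA.1697 without Y1F replicate 1 or 2. Over the 13 adjacent IDs of the run WT had 7912 counts, S2A 17969, S7A 7522 and Y1F 82.

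**Figure D3:**
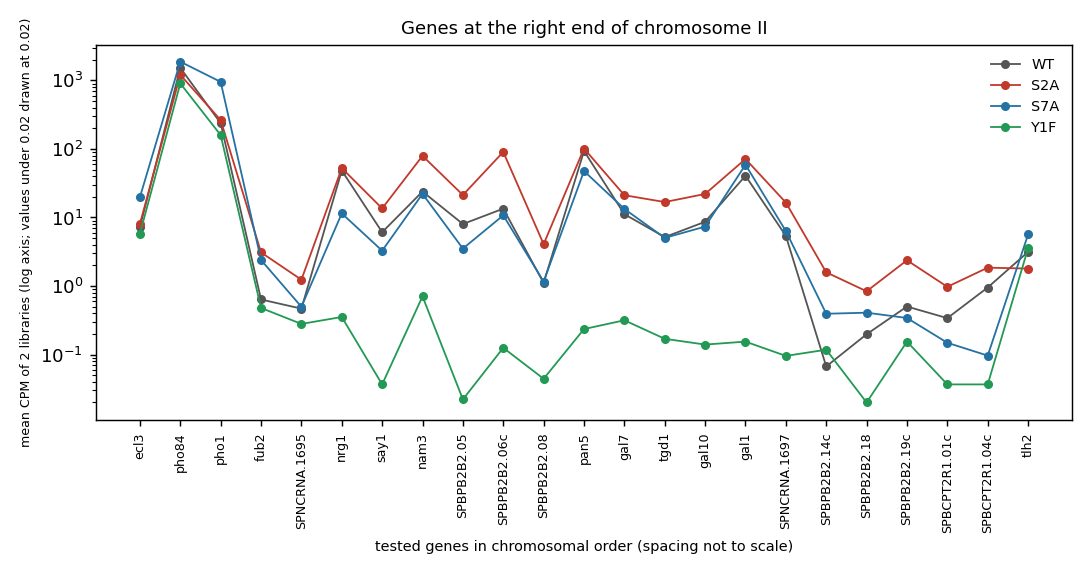
Mean CPM on a log axis for the tested genes at an end of chromosome II, in chromosomal order from ecl3 to tlh2 with even spacing that is not to scale, 1 line per strain and values under 0.02 CPM drawn at 0.02. The Y1F line drops below those of the other strains over the run from nrg1 to SPNCRNA.1697, which held 82 counts in Y1F and 7912 in WT.

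Many subtelomeric genes outside that run were lower in Y1F too. Of 80 subtelomeric genes 49 were lower, 0 higher and 31 not called (51 lower adjusted over the list alone; median −1.31, or −1.28 with bounds; camera adjusted p = 9.10e-48). The adjusted p = 0.0643 with an estimated correlation. Without the run, a choice made after seeing the data, 39 of 70 were lower and 0 higher (median −1.04, camera adjusted p = 2.41e-23). For these 70 the adjusted p = 0.0910 with an estimated correlation. Some of these genes have near-identical copies at other chromosome ends, which limits single values. SPBPB10D8.02c fell from 22.9 ± 5.56 to 0.301 ± 0.301 CPM (−6.47 ± 0.355; −7.90 without Y1F replicate 1, −5.45 without Y1F replicate 2). Flocculins fell, 7 of 10 lower, 1 higher and 2 not called (8 and 2 adjusted over the list alone; median −0.70, camera adjusted p = 5.25e-06), with pfl7 at −4.40 ± 0.308, pfl9 at −1.79 ± 0.283, pfl8 at −1.63 ± 0.152 and pfl3 at −1.12 ± 0.072. The adjusted p = 0.0715 with an estimated correlation.

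Histone genes rose in Y1F, 9 of 10 higher, 0 lower and 1 not called, also adjusted over the list alone (median 0.47, camera adjusted p = 3.17e-10). The adjusted p = 0.0643 with an estimated correlation. hta1 went from 480 ± 27.9 to 824 ± 7.02 CPM (0.78 ± 0.049, adjusted p = 2.10e-07), hhf2 rose by 0.60 ± 0.047 and htb1 by 0.51 ± 0.050, with near-identical copies limiting single values. Ribosomal protein genes fell, 107 of 131 lower, 1 higher and 23 not called (117 and 1 adjusted over the list alone; median −0.23, camera adjusted p = 2.39e-10), with rpl1002 at −0.45 ± 0.058. The adjusted p = 0.924 with an estimated correlation. mei2 fell from 82.8 ± 7.60 to 17.1 ± 2.82 CPM (−2.25 ± 0.1198, adjusted p = 4.77e-08) and mfm2 by −1.05 ± 0.113. The Ste11 list fell, 5 of 10 lower, 0 higher and 5 not called, also adjusted over the list alone (median −0.22, camera adjusted p = 0.0230). The adjusted p = 0.868 with an estimated correlation, and without Y1F replicate 1 it was 0.0626. ste11 was at −0.33 ± 0.094 (adjusted p = 0.0156), and not called without WT replicate 2 (−0.25, adjusted p = 0.0988) or Y1F replicate 1 (−0.28, adjusted p = 0.0806). Marker genes of strain background fell slightly (4 of 6 lower, 0 higher, 2 not called, also adjusted over the list alone; median −0.26, camera adjusted p = 0.0339), with lys1 at −0.50 ± 0.048. The adjusted p = 0.868 with an estimated correlation, and without WT replicate 1 it was 0.104.

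Among genes that rose in Y1F, mpn1 went from 11.7 ± 1.86 to 56.8 ± 3.29 CPM (2.29 ± 0.098, adjusted p = 5.65e-09), gnr1 from 5.20 ± 0.317 to 21.8 ± 0.813 CPM (2.06 ± 0.121), SPAPB18E9.04c from 20.3 ± 0.397 to 71.8 ± 11.2 CPM (1.84 ± 0.116) and the metallothionein gene zym1 from 7.73 ± 2.68 to 23.8 ± 0.574 CPM (1.61 ± 0.178). Meiosis genes were not called as a list (8 higher, 2 lower of 22; adjusted p = 0.141), with dmc1 at 2.25 ± 0.222, meu14 at 1.56 ± 0.210 and spo6 at −1.86 ± 0.275. The copper transporter ctr4 was at 89.7 ± 76.5 against 30.7 ± 4.87 CPM (1.49 ± 0.469, adjusted p = 0.0274) and was not called without WT replicate 1 (1.32, adjusted p = 0.12), WT replicate 2 (1.65, 0.0640) or Y1F replicate 1 (0.21, 0.449), or with DESeq2 (0.0996); without Y1F replicate 2 it was at 2.23 (3.91e-06). The phosphate list was not called (1 of 3 higher, 2 lower; adjusted p = 0.415, or 0.0396 without WT replicate 2), with pho84 at −0.76 ± 0.086 (adjusted p = 3.68e-05), pho1 at −0.58 ± 0.110 (adjusted p = 0.00161) and tgp1 at 0.59 ± 0.130 (adjusted p = 0.00440). The serine 2 kinase lsk1 was at 0.08 ± 0.044 (adjusted p = 0.159), set2 at −0.09 ± 0.044 (adjusted p = 0.132; 0.0441 without WT replicate 2) and pcf11 at 0.17 ± 0.047 (adjusted p = 0.0120), the last not called as a gene without WT replicate 1 (0.16, 0.0531), Y1F replicate 1 (0.16, 0.0711) or Y1F replicate 2 (0.19, 0.0503) and with DESeq2 (0.0977). The 3′ end processing list had 8 of 17 higher and 0 lower in Y1F (adjusted p = 0.358), and RNA surveillance and RNAi 4 of 12 higher and 0 lower (7 higher adjusted over the list alone; adjusted p = 0.271), neither called.

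Neither list of noncoding RNAs by overlap was called in Y1F. Of 584 antisense RNAs 106 were higher and 96 lower (median 0.05, camera adjusted p = 0.616), and of 324 other noncoding RNAs 19 were higher and 67 lower (median −0.19, or −0.20 with bounds; adjusted p = 0.0903, and 0.0406 without WT replicate 1). SPNCRNA.679 rose from 3.85 ± 0.487 to 15.7 ± 0.638 CPM (2.03 ± 0.141) and SPNCRNA.997 from 0.167 ± 0.0418 to 1.14 ± 0.464 CPM (2.79 ± 0.530). The mitochondrial genome had 2 of 36 transcripts higher and 0 lower (adjusted p = 0.642). That list pointed up at an adjusted p of 0.000175 without WT replicate 2 and down at 0.492 without WT replicate 1. Nuclear transfer RNA genes had 2 of 42 higher and 0 lower (median 0.09).

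Compared directly, antisense RNAs as a list were higher in S2A than in S7A and in Y1F. Between S2A and S7A 3317 genes differed (1765 higher in S2A, 1552 lower, or 1922 and 1367 with scaling on protein-coding genes; 677 by at least 2-fold). Antisense RNAs were higher in 401 of 584 cases, lower in 35 and not called in 148 (411 and 37 adjusted over the list alone; median 0.98, camera adjusted p = 1.86e-26). The adjusted p = 0.0729 with an estimated correlation. All noncoding RNAs had 594 of 1104 higher, 82 lower and 428 not called (604 and 85 adjusted over the list alone; median 0.61, adjusted p = 3.13e-14). The adjusted p = 0.144 with an estimated correlation. The 3 phosphate genes were lower in S2A, also adjusted over the list alone (median −1.86, adjusted p = 9.58e-06), with tgp1 at −2.34 ± 0.100. The adjusted p = 0.339 with an estimated correlation. fio1 stood 3.11 ± 0.322 higher in S2A, with 7 of 9 iron acquisition genes higher, 0 lower and 2 not called (8 adjusted over the list alone; median 1.10, adjusted p = 0.00878). The adjusted p = 0.651 with an estimated correlation. gdt1 was higher by 7.53 ± 0.159, SPAPB18E9.04c by 3.04 ± 0.118 and SPBPB2B2.06c by 3.04 ± 0.136, while mfm2 (−2.22 ± 0.167), SPCC965.14c (−2.05 ± 0.168) and SPCC1620.13 (−2.03 ± 0.142) were lower.

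Further lists differed between S2A and S7A. Flocculins were higher in S2A (7 of 10, 0 lower, 3 not called, also adjusted over the list alone; median 0.54, adjusted p = 0.000241). The adjusted p = 0.144 with an estimated correlation. All 5 thiamine genes were higher, also adjusted over the list alone (median 0.41, adjusted p = 0.0431, and 0.0559 without S2A replicate 2). The adjusted p = 0.549 with an estimated correlation. Cell separation genes were lower (6 of 8, 0 higher, 2 not called, also adjusted over the list alone; median −0.41, adjusted p = 0.00878). The adjusted p = 0.621 with an estimated correlation. Mitochondrial transcripts were lower (11 of 36, 0 higher, 25 not called; 8 adjusted over the list alone; median −0.23, adjusted p = 0.0431). The adjusted p = 0.835 with an estimated correlation, and the call was lost without S2A replicate 2 (0.0794) or S7A replicate 1 (0.0754). Not called in S2A against S7A, but called with a replicate block, were meiosis genes (10 higher, 2 lower of 22; adjusted p = 0.0599, 0.0454 with the block), Tf2 retrotransposons (5 of 5 higher, near-identical copies; 0.0633, 0.0454) and subtelomeric genes (35 higher, 17 lower of 80; 0.0576, 0.0367). Without S2A replicate 1 these had 0.0340, 0.0226 and 0.0397; meiosis had 0.0477 without S2A replicate 2, and subtelomeric genes 0.0329, 0.0376 and 0.0393 without WT replicate 1, WT replicate 2 and S7A replicate 2 and 0.0434 with RLE scaling. The Ste11 list (adjusted p = 0.146) had 0.0386 without S7A replicate 2.

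Between S2A and Y1F 3051 genes differed (1569 higher in S2A, 1482 lower, or 1793 and 1249 with scaling on protein-coding genes; 561 by at least 2-fold). Antisense RNAs were higher in 351 of 584 cases, lower in 44 and not called in 189 (364 and 50 adjusted over the list alone; median 0.81, camera adjusted p = 1.68e-22). The adjusted p = 0.113 with an estimated correlation. All noncoding RNAs had 476 higher, 122 lower and 506 not called (485 and 129 adjusted over the list alone; median 0.41, also with bounds; adjusted p = 4.92e-09). The adjusted p = 0.204 with an estimated correlation. Subtelomeric genes were higher in S2A (53 of 80, 3 lower, 24 not called; 55 and 3 adjusted over the list alone; median 1.88, also with bounds; adjusted p = 1.06e-27). The adjusted p = 0.136 with an estimated correlation. The largest of these were pan5 (8.79 ± 0.133), gal1 (8.94 ± 0.157; 9.54 without Y1F replicate 1, 8.29 without Y1F replicate 2), SPBPB2B2.06c (9.28 ± 0.284; 10.12 without Y1F replicate 2) and SPBPB2B2.05, with 1 count in Y1F and a ratio of 768 (138 to 30380; model value 9.26, or 11.49 without Y1F replicate 2). mfm2 (−2.54 ± 0.163), ste4 (−2.26 ± 0.133), atl1 (−1.93 ± 0.208) and SPCC965.14c (−1.89 ± 0.172) were lower in S2A.

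More lists separated S2A from Y1F. Flocculins were higher in S2A (8 of 10, 1 lower, 1 not called, also adjusted over the list alone; median 1.20, adjusted p = 2.83e-08). The adjusted p = 0.113 with an estimated correlation. Histones were lower (9 of 10, 1 higher, 0 not called, also adjusted over the list alone; median −0.47, adjusted p = 9.90e-07). The adjusted p = 0.113 with an estimated correlation. Mitochondrial transcripts were higher (32 of 36, 0 lower, 4 not called; 33 adjusted over the list alone; median 0.67, adjusted p = 1.52e-05). The adjusted p = 0.713 with an estimated correlation. Cell separation genes were lower (7 of 8, 0 higher, 1 not called, also adjusted over the list alone; median −0.36, adjusted p = 0.000925). The adjusted p = 0.479 with an estimated correlation. Ste11 genes were lower (6 of 10, 1 higher, 3 not called; 6 and 2 adjusted over the list alone; median −0.56, adjusted p = 0.00188). The adjusted p = 0.479 with an estimated correlation. Core stress genes were higher (6 of 15, 4 lower, 5 not called, also adjusted over the list alone; median 0.19, adjusted p = 0.0367). The adjusted p = 0.479 with an estimated correlation, and the call was lost without S2A replicate 1 (0.0809) or Y1F replicate 1 (0.0943).

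Between Y1F and S7A 3042 genes differed (1606 higher in Y1F, 1436 lower; 429 by at least 2-fold). The 3 phosphate genes were lower in Y1F, also adjusted over the list alone (median −2.58, camera adjusted p = 1.42e-11). The adjusted p = 0.258 with an estimated correlation. Subtelomeric genes were lower (49 of 80, 3 higher, 28 not called; 49 and 4 adjusted over the list alone; median −1.32, also with bounds; adjusted p = 5.33e-22). The adjusted p = 0.258 with an estimated correlation. All 36 mitochondrial transcripts were lower in Y1F, also adjusted over the list alone (median −0.996, adjusted p = 1.88e-14). The adjusted p = 0.602 with an estimated correlation. Core stress genes were lower (8 of 15, 2 higher, 5 not called, also adjusted over the list alone; median −0.41, adjusted p = 6.74e-06). The adjusted p = 0.258 with an estimated correlation. Histones were higher (8 of 10, 0 lower, 2 not called, also adjusted over the list alone; median 0.25, adjusted p = 0.0113). The adjusted p = 0.258 with an estimated correlation. Thiamine genes were higher (4 of 5, 0 lower, 1 not called, also adjusted over the list alone; median 0.41, adjusted p = 0.0375, and 0.0732 without S7A replicate 2). The adjusted p = 0.602 with an estimated correlation. Antisense RNAs had 152 of 584 higher and 77 lower and were not called as a list (adjusted p = 0.263). Iron acquisition was not called either (5 higher, 0 lower of 9; adjusted p = 0.0692), but was with a replicate block (0.0452), with RLE scaling (0.0483) and without WT replicate 1 (0.0392), WT replicate 2 (0.0484), S7A replicate 1 (0.0350), Y1F replicate 1 (1.71e-09) or Y1F replicate 2 (0.00654).

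Single genes also parted Y1F from S7A. gal1 was lower in Y1F by −8.66 ± 0.161 (−9.27 without Y1F replicate 1, −8.02 without Y1F replicate 2) and pan5 by −7.70 ± 0.150. SPBPB2B2.05 had 1 count in Y1F, lower by a ratio of 130 (23.0 to 5171; model value −6.69, or −8.92 without Y1F replicate 2), and SPAC212.04c had 3, lower by a ratio of 103 (35.0 to 503). SPAPB18E9.04c (2.61 ± 0.12), mug94 (2.57 ± 0.141) and mpn1 (2.45 ± 0.094) were higher in Y1F. fio1 was also higher (287 ± 180 against 44.1 ± 9.47 CPM; 2.73 ± 0.321, or 1.88 without Y1F replicate 2).

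Many genes were called in more than 1 mutant. Of genes called in both S2A and S7A 1493 changed the same way and 388 in opposite ways, with 723 higher and 770 lower in both, where independent lists would share 415.8 and 402.3. For S2A and Y1F 1269 went the same way and 213 opposite (660 higher and 609 lower in both, against 316.4 and 289.1), and for S7A and Y1F 964 and 319 (407 and 557, against 253.8 and 263.9). The comparisons share the WT libraries, so independence is not the value to be met without shared effects, and unchanged groups were simulated against WT 20 times for the covariance. The covariance of log2 fold changes across genes was 0.238 for S2A and S7A, 0.162 for S2A and Y1F, and 0.126 for S7A and Y1F, where the simulations gave 0.0131, 0.0129 and 0.0129. On protein-coding genes alone the covariances were lower, at 0.122, 0.0754 and 0.0658, and no simulation was run for these genes alone. In the simulations the mean number of genes called the same way was 0.2, 0.3 and 0.25, and at most 3. No gene was changed in them, so few could be called, and these counts cannot be set against those observed. Pearson correlations were 0.501, 0.338 and 0.373, against simulated means of 0.548, 0.533 and 0.542. Those simulated means came from groups with no changed gene, where noise of the shared control makes up much of each fold change. The data hold many changes, so a shared control alone need not give correlations of that size there. The correlations are therefore not used for or against shared changes, and the covariances are the closer comparison. The simulated covariances already hold the noise of the shared controls at the fitted spread. With 2 WT libraries the controls cannot be split into parts of 2, so a deviation of the WT libraries beyond that spread may still add to the excess. The mutants also share the kanMX6 marker at rpb1 and a lower rpb1 level, so shared changes cannot be assigned to the residue changes. In all 3 mutants 277 genes were higher and 384 lower, where independent lists would share 73.1 and 70.1. As for the pairs, the shared WT libraries mean that independence is not the value to be met. Of the lower genes 60 encode ribosomal proteins, against 0 of the higher.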

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

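The tests of the antisense rise were chosen before its result was seen, and those of the Y1F run and of the mitochondrial and transfer RNA rise were chosen only after theirs. Intervals in this part are 95% bootstrap intervals from 10000 resamples of RNAs or genes, not of libraries. They take the RNAs or genes as independent and do not cover the spread between libraries.

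Counting without regard to strand could affect the antisense rise in S2A: among 148 such RNAs lying wholly inside 1 coding gene of the other strand, the WT ratio of noncoding to coding read density had a median of 0.0305 (quartiles 0.0052 to 0.126). Unstranded counting would give a median of 1 or more, or of 0 where reads are dropped as ambiguous, but only 10 of the 148 had 0 counts and the values met the bound written beforehand against both forms (median above 0 and below 0.5, upper quartile below 1), which argues against this explanation. More sense reads on the wrong strand in S2A would set a floor under the antisense to sense ratio. Its 10th percentile over the 148 RNAs in S2A was 0.00382 (interval 0.00062 to 0.0148). The median gain was 0.137, taken only over the 98 of these RNAs already called higher in S2A. The 10th percentile met the bound written beforehand, 0.1 of the gain, but the upper end of its interval did not. The looser bound of 0.5 of the gain was chosen after the result was seen. The 391 antisense RNAs with no coding gene on their strand ending within 1 kb upstream still had a median change of 0.744 (interval 0.618 to 0.845). Those with such a gene upstream had 1.34, so read-through may account for part of the rise.

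The run of adjacent genes near 0 in Y1F could be a deletion in that strain. Of the IDs of the run, 11 had at least 5 CPM in WT, and the highest Y1F level among them was 3.28% of WT (median 0.933%). Over the whole run 82 counts remained in Y1F. Loss of the DNA could give values this low, but the run was picked because its genes were near 0 in Y1F. The outcome was thus fixed by that choice and cannot count for a deletion. Strong local silencing would give the same counts and was not tested, and RNA counts cannot show DNA. The other 70 subtelomeric genes had a median of −1.04 (interval −1.38 to −0.651), with 39 lower and 0 higher. The run was picked for its depth, so a smaller median outside it was to be found either way. Single genes outside it also fell far, such as SPBPB10D8.02c at −6.47. The median therefore cannot decide whether a general but uneven subtelomeric fall reached this depth in the run.

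The rise of mitochondrial transcripts and nuclear transfer RNAs in S2A and S7A could reflect library making. Less complete removal of ribosomal RNA would not lift the 11 mitochondrial genes that are not transfer RNAs by ID, which had a median of 0.555 in S2A (interval 0.46 to 0.968) and 0.685 in S7A. All 11 were among the transcripts already called higher in both mutants. Their rise is thus part of the pattern to be explained, and it is no separate test of this cause. More short RNA kept in the libraries would lift the 44 small nuclear and nucleolar RNAs, which had −0.017 in S2A (interval −0.193 to 0.115) and −0.103 in S7A. Other causes in library making were not tested.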

How the results depend on the processing

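The alternatives of scaling, filtering and modelling were chosen before the results, and the reruns without SPNCRNA.98 only after. Requiring a 2-fold change left 658, 395 and 271 genes for S2A, S7A and Y1F against WT, 677 for S2A against S7A, 561 for S2A against Y1F and 429 for Y1F against S7A. With the correlation estimated in camera, 0 lists were called in S2A, 0 in S7A and 0 in Y1F against WT, 0 in S2A against S7A, 0 in S2A against Y1F and 0 in Y1F against S7A. With 1 library left out, genes changed in Y1F ran from 1203 (without Y1F replicate 2) to 2184 (without S2A replicate 1). Lists called in S2A against S7A ran from 7 to 11, in S2A against Y1F from 8 to 12 and in Y1F against S7A from 5 to 9. The noncoding share of counts was 1.22%, 1.61%, 1.21% and 1.09% in WT, S2A, S7A and Y1F, and 0.834%, 1.14%, 0.675% and 0.851% without SPNCRNA.98. With SPNCRNA.98 kept, Y1F had 1.13% over protein-coding and noncoding counts alone. DESeq2 gave 251, 125 and 184 genes called in opposite directions for S2A and S7A, S2A and Y1F, and S7A and Y1F, and 638 called alike for the last; on protein-coding genes r was 0.268 for S2A and Y1F and 0.302 for S7A and Y1F. These turned in direction: the S7A antisense rho (0.013 with any overlap), pho1 in S2A (0.369 without WT replicate 1, −0.043 without WT replicate 2), and adjusted list p for Y1F iron acquisition (0.0131 without Y1F replicate 1 to 0.917 without WT replicate 1; down at 0.506 without Y1F replicate 2), Y1F mitochondrial genes (0.000175 without WT replicate 2 to 0.9 without Y1F replicate 2; down at 0.492 without WT replicate 1), Y1F small nuclear and nucleolar RNAs (0.0406 without WT replicate 1 to 0.837, up, without WT replicate 2) and copper uptake in S2A against Y1F (0.0361 without Y1F replicate 2 to 0.847 without S2A replicate 1; up at 0.524 without Y1F replicate 1). The cause was not tested for any of these.

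Libraries share only a replicate number. With that number as a block 3403, 2879 and 2078 genes were called for S2A, S7A and Y1F against WT. Correlations of replicate differences between strains ran from −0.163 (WT and S2A) to 0.178 (WT and Y1F).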

Other observations

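The genes of this part, and their description, were chosen only after their values were seen. SPAC186.06, next in ID to gdt1, had 0 counts in WT and was at least 11.3-fold higher in S2A (model value 7.32, against 6.47 with DESeq2). SPBC460.05 stood at 30.2 ± 3.57 CPM in WT and changed by −5.18, −5.44 and −5.43 in S2A, S7A and Y1F, and SPBC460.04c at 13.3 ± 1.16 CPM, with −5.25, −4.92 and −5.54. Both fell to a like depth in every mutant. The mutants also share a marker at rpb1 that WT lacked, so these falls cannot be assigned to the residue changes. yhb1 stood at 85.8 ± 0.955 CPM in WT and 20.03 ± 1.91 in Y1F (−2.11), and sul2 fell by −0.92, −0.42 and −1.49.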
